A study of Mus musculus with 2 samples.

How the data were processed

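ChIP-seq libraries were made from doxycycline-induced C2C12 cells of a single MMH clone, with DNA sheared to 150 to 600 bp per the labels' protocols. The grouping followed the antibody label of each sample, which gives 1 library with DUX4 antisera and 1 with HA antibody. The labels conflict over the control: the series' design text names a GFP antibody where the sample label names HA. The HA label was used, and which antibody was in the tube could not be settled from the sources used here.

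The submitters' processing notes name BWA and MACS2 and the build mm10. Per the file headers, the authors called peaks with MACS version 2.1.0.20151222 on paired-end fragments of the antisera library against the control library, with a q-value threshold of 0.01, an effective genome size of 1870000000 and at most 1 fragment kept per position. The file headers give the depth used above and a redundant share of 20% for the antisera library and 42% for the control. Read mapping settings, filters on mapping quality and any exclusion of problematic regions are not given in the sources used here. Per the file headers, the deposited pileup is a signal, the number of antisera fragments over the summit. The authors' peak caller gave −log10 of the p-value and of the q-value for each peak, and the deposited fold enrichment is the ratio of the pileup plus 1 to the local background plus 1. The list is 1 immunoprecipitation against 1 control, called once, so peaks have no replicate check, and their scores were used only to describe, rank and select peaks within the list.

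The local background was recovered from the deposited pileup and fold with that pseudocount of 1. It was checked by recomputing the Poisson −log10 p, which matched within 1% for 100% of the 50196 peaks with a finite computed value. The lowest background, 4.01 fragments, was shared by 78.0% of peaks (tolerance 0.001) and is called the floor. Background values are therefore informative only where they exceed that floor. Poisson intervals of pileups and binomial intervals of shares are at 95% and cover counting error only, not variation between cultures or immunoprecipitations.

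Genes came from a RefSeq table for GRCm38.p6, whose primary assembly is that of mm10, with 49980 positioned genes, of which 21900 are protein-coding. The table gives spans without strand, exons or sequence. The plan set before the data were examined had used the 5 prime gene end, exon and UTR classes, Dux and DUX4 motif shares, substitutions of the Dux core and repeat-masked bases. The nearer of both gene ends replaced the 5 prime end throughout, and the motif, substitution, exon, UTR and repeat results were not analysed here. Names of list members were matched to symbols and synonyms, and 3 entries found no match.

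Locations of summits on the autosomes and X were compared with 10 random positions per peak on the same chromosome by 2-sided Fisher exact tests. The random positions were drawn over the chromosome spans and not over mappable bases, since no sequence was used here. For each of 11 gene lists, genes with a summit within 5 kb of either end were compared with all other protein-coding genes by 2-sided Fisher exact tests with Benjamini-Hochberg adjustment over the lists. Neighbouring genes can share a peak, so they are not independent. For that reason each count was also set against 1000 circular shifts of all peaks along their chromosomes, which was added after the data were examined. The mean log2 of the best fold enrichment per gene was compared by permutation with 100000 resamples. Odds ratios had 0.5 added to each cell.

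Named genes followed a rule set before the data were examined: the 25 protein-coding genes with an end within 5 kb of the peaks with the largest −log10 p, 1 gene (the nearest) per peak and 1 peak per gene, at most 4 members of each list by strength, and the 10 strongest peaks. Members beyond that number, the 3 peaks of highest fold, the parts of lists and the peak between the *Zscan4* copies were named after their values were seen. Alternatives were stricter q-values, the strongest 10% of peaks, other distances, the gene body, flanks, 1 bp of overlap, and 1 gene per 200 kb block. Those added later were length matching, protein-coding members alone, removal of peaks with a local background of 10 or more, and removal of chromosomes 4 and 15. The 200 kb blocks were first counted by any gene with a peak. Counting the first gene of each block, called 1 gene per block, replaced this after its values were seen.

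The procedure was tested on simulated data over 21900 genes. In a list of 200 genes, a part was given a planted peak within 5 kb of a gene end, and the list's odds ratio was 4.89. That 100% of the planted peaks were found was fixed by this placement, so it does not check the procedure. In 100 random placements of the peaks, the Fisher test called the 2-cell list 2 times, the DUX4-target list 1 time, housekeeping 1, pluripotency 2, skeletal muscle 4, Hox 6, ribosomal protein 8, Obox and paired-like 9, p53 and cell death 0, vomeronasal 62 and olfactory 100 times. The test is therefore biased for the 2 receptor lists, and the source of the bias was not tested in these placements. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.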

Results

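Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in C2C12 cells, an established line of mouse myoblasts, to map where the DNA-binding part of mouse Dux sits in the genome. Dux and its human relative DUX4 are double-homeodomain transcription factors that act in the early embryo. The cells came from a single clone carrying a doxycycline-inducible transgene, MMH, which joins the homeodomains of mouse Dux to the carboxy-terminal part of human DUX4, so that antisera raised against DUX4 can precipitate it. Cells were induced for 18 h with 2 ug/ml doxycycline. The 2 libraries were 1 immunoprecipitation with the DUX4 antisera MO488 and MO489 and 1 control immunoprecipitation, labelled as HA antibody, from induced cells of the same line. Per the file headers, the peak caller took 32659686 fragments of the antisera library, of which 26253175 remained after duplicate removal. From the control library it took 40115471, of which 23412256 remained. With 1 library per group no difference between replicates could be measured, so every test below compares positions or genes within a single peak list and does not cover variation between cultures. The human DUX4 data that the study compared with this experiment were not analysed here.

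The first question was where and how strongly the chimera was enriched. The authors' deposited table held 51356 peaks in mm10 coordinates, each with the authors' own pileup, −log10 p and fold enrichment over local background. Median peak width was 430 bp (range 287 to 5080 bp), median pileup at the summit was 41 fragments and median fold enrichment was 8.02 (range 1.70 to 405). Enrichment reached 100-fold or more at 83 peaks and stayed under 5-fold at 8473 peaks (16.5%). The highest fold enrichment, 405, lay at 50955051 to 50956079 on chromosome 7, 2561 bp from the pseudogene *Gm21033*. The next, 365, lay at 21602857 to 21604240 on chromosome 19, within the protein-coding gene *1110059E24Rik*. The third, 333, lay at 59608062 to 59609914 on chromosome 16, 3904 bp outside the nearer end of *Arl6*, which encodes a small GTPase of the primary cilium.

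Ranked by −log10 p, 4 of the 10 strongest peaks had low enrichment over a very high local background. The highest-ranked, at 3023212 to 3026057 on chromosome 9, had a pileup of 27027 fragments against a background of 5204, a 5.19-fold enrichment. The second, at 98666570 to 98667360 on chromosome 2, had 72123 against 32307, or 2.23-fold. The other two lay within the same chromosome 9 region, at 3.28-fold and 2.85-fold. Across the list, 117 peaks (0.228%) had a local background of 10 fragments or more.

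**Figure D1:**
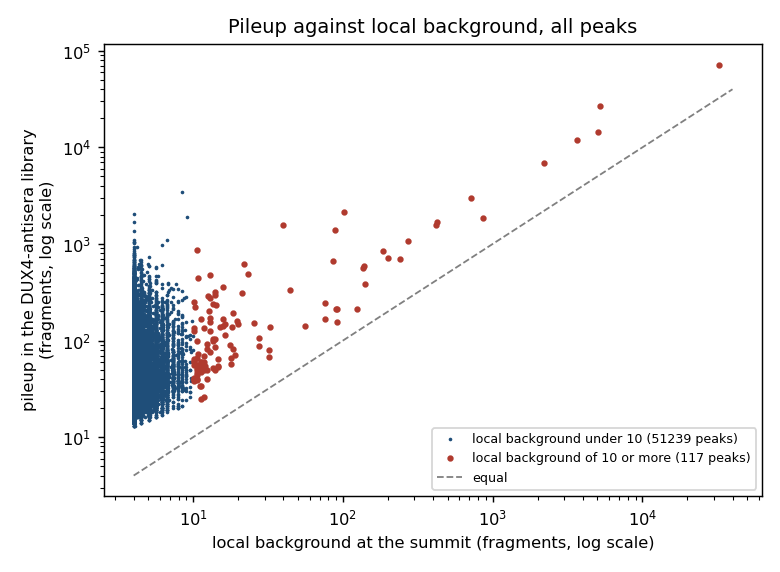
Pileup at each peak summit in the DUX4-antisera library (vertical, fragments, log scale) against the local background recovered from the deposited fold enrichment (horizontal, fragments, log scale). Each point is 1 peak, the dashed line marks equal values, and the 117 red points are peaks with a background of 10 fragments or more, which reach a background of 32307.

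The peaks lay across genes and intergenic DNA in nearly the proportions of random positions. Summits fell inside a gene in 24652 of 51354 peaks on the autosomes and X (48.0%, exact binomial 95% interval 47.6 to 48.4%), against 48.6% of random positions on the same chromosomes (odds ratio 0.975, 2-sided Fisher exact p = 0.00621, Benjamini-Hochberg adjusted p = 0.0394 over the location tests). Against flanks 2 kb away the difference no longer passed (odds ratio 0.983, Fisher exact p = 0.112), and in the strongest 10% of peaks its direction was reversed (odds ratio 1.05, p = 0.0923). Summits within 1 kb of either end of a protein-coding gene made up 3.05% of peaks (interval 2.90 to 3.20%) against 2.98% of random positions (odds ratio 1.02, Fisher exact p = 0.415). Within the list, the strongest 10% by −log10 p lay inside a gene more often than the weakest 10%, at 49.8% against 47.0% (odds ratio 1.12, Fisher exact adjusted p = 0.0134 over 3 tests), but the shares inside protein-coding genes, 40.1% and 39.0%, did not pass (adjusted p = 0.276). The strongest 10% lay within 1 kb of a coding gene end less often, at 2.88% against 3.68% (odds ratio 0.777, Fisher exact adjusted p = 0.0348). Over all strength classes of 10% each, the share inside a gene ranged from 46.6 to 49.8% without a steady order, and the share within 1 kb of a coding gene end was 2.71 to 3.23% in every class but the weakest.

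The genes next to the strongest peaks included many that are active in the mouse embryo at the 2-cell stage. Of the 25 protein-coding genes named by the strongest peaks, taking for each peak only the nearest gene with an end within 5 kb, 7 belonged to a list of genes of the 2-cell programme, which holds 0.215% of all coding genes. These were *Zscan4b*, *Zscan4c*, *Zscan4d* and *Zscan4f*, which encode SCAN-domain zinc-finger proteins used as markers of that stage, *Usp17le* of a deubiquitinase family, and *Pramel11* and *Pramel19* of the Prame-like family. Most of the 7 are copies of the *Zscan4* and Prame-like families, which may share reads, so they are not independent cases. Fold enrichment was 143 at *Pramel19* (95% Poisson interval of the pileup, background held fixed, 134 to 151) and 83.8 at *Pramel11* (76.0 to 92.2). At *Usp17le* it was 73.9 (69.0 to 79.0), over a raised local background of 10.7 fragments. The Prame-like genes *Pramel18* (152-fold) and *Pramel24* (85.4-fold), which were outside that list, were also among the 25.

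The rest were also outside that list, although the *LOC100504180* peak lay within 5 kb of *Duxf3*, a member of it. *Arl6* came first. *Tmem156* (148-fold) and *Tmem131* (125-fold) encode transmembrane proteins, with the *Tmem131* summit inside the gene, 2140 bp from its nearer end. *Dact3*, a regulator of Wnt signalling, had 111-fold enrichment 473 bp outside the gene. *Tnrc6b*, of the microRNA silencing machinery, had 97.4-fold enrichment inside the gene. *Trim72*, which takes part in membrane repair of muscle fibres, had 91.2-fold enrichment 3620 bp outside the gene. The remaining genes were *D830031N03Rik*, *Gm21761*, the F-box gene *Fbxo24*, *Gimap3*, *Nkain2*, *Etfbkmt*, *Fam207a*, *Abhd3*, *Btbd1* and *LOC100504180*, with fold enrichment from 38.7 at *LOC100504180* to 113 at *D830031N03Rik*. Summits lay inside 8 of the 25 genes.

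All 9 *Zscan4* genes and pseudogenes had a peak of their own on chromosome 7 between 10.8 and 11.6 Mb. Fold enrichment ranged from 107 at *Zscan4-ps1* (interval 97.7 to 116) to 178 at *Zscan4c* (167 to 190). Each summit lay outside its gene, 147 to 313 bp from the nearer end, and 8 of the 9 lay within 200 bp of it. The *Zscan4c* peak spanned 11003962 to 11006046, beside a gene annotated from 11005745 to 11010547, with a pileup of 924 fragments. The *Zscan4d* peak, 5080 bp wide, was the widest in the list. The highest fold enrichment of this region, 210 at 11476219 to 11478893, lay between the copies, 9227 bp from the pseudogene *Gm7207*. The copies are near-identical in sequence and the handling of reads that map to several places is not given in the sources used here, so the share of each copy in these pileups is uncertain.

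**Figure D2:**
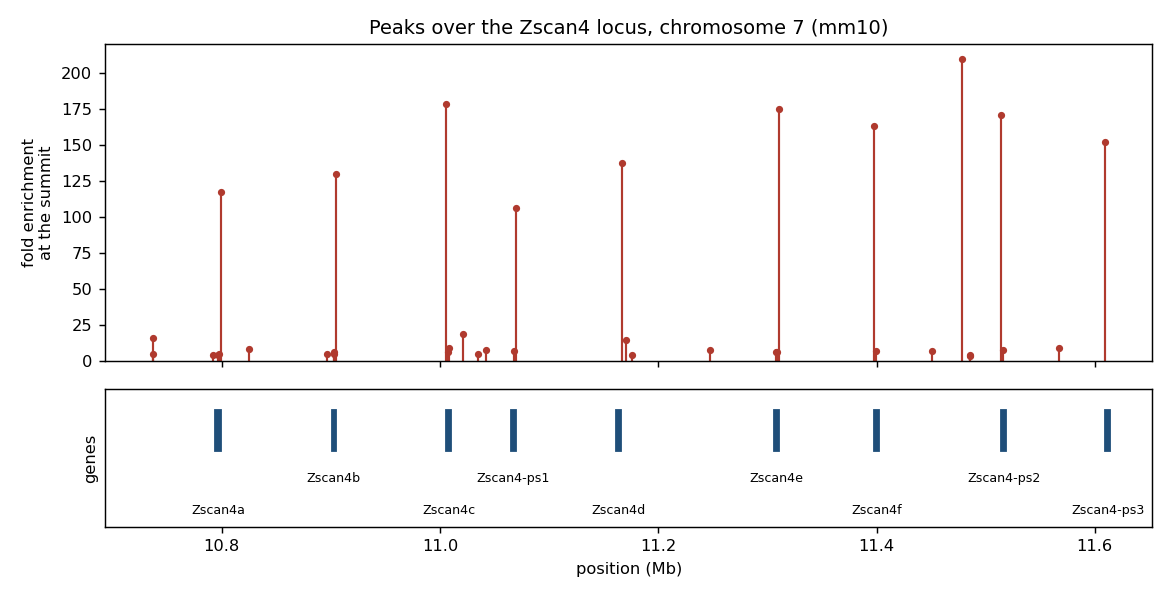
Fold enrichment at every peak summit (upper panel, vertical lines) along chromosome 7 in Mb over the *Zscan4* region, with the 9 annotated *Zscan4* genes and pseudogenes as boxes (lower panel). A peak of 107-fold to 178-fold stands beside each copy, and the highest, 210-fold, stands between *Zscan4f* and *Zscan4-ps2*.

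The second question was which groups of genes the peaks lay near, tested on 11 lists fixed before the data were examined. A peak summit lay within 5 kb of either gene end for 43 of 53 members of the 2-cell list (81.1%, exact interval 68.0 to 90.6%), against 5990 of 21853 other protein-coding genes (27.4%; odds ratio 11.0, 2-sided Fisher exact adjusted p = 3.54e-15). Besides *Zscan4*, 5 of 6 *Usp17l* members, 8 of 10 Prame-like members and 4 of 8 *Tdpoz* members had a peak, families picked out after their values were seen. The *Tdpoz* share did not pass against other coding genes (odds ratio 2.63, Fisher exact adjusted p = 0.293). Of the single genes, *Zfp352*, *Tmem92*, *Arg2*, *Nelfa* and *Ubtfl1* had a peak within 5 kb and *Sp110* had none. The peak nearest to *Duxf3*, a copy of Dux itself, lay 3977 bp from the gene with 38.7-fold enrichment. Its summit lay inside *LOC100504180*, the nearer gene, so that *Duxf3* was not counted among the 25. The local background there was 39.8 fragments, against a floor of 4.01. Reads from the transgene, which carries homeodomains of mouse Dux, were not told apart here from reads of this locus. Binding at *Duxf3* is therefore uncertain. Among genes with a peak, the best peak of a 2-cell gene had a median fold enrichment of 34.9, against 8.98 for other coding genes. The mean log2 fold enrichment was higher by 1.78 (permutation p = 1e-05, the smallest that 100000 permutations can give). That permutation treats family copies as independent genes, and 9 of the 10 members at 100-fold or more were *Zscan4* copies. Fold enrichment at the single genes was 34.9 for *Zfp352*, 25.5 for *Tmem92*, 13.2 for *Arg2*, 10.4 for *Ubtfl1* and 8.78 for *Nelfa*. When all peaks were shifted together along each chromosome, a mean of 12.5 members had a peak, and 0 of 1000 shifts reached 43. In the gene body alone the difference did not pass (odds ratio 1.29, Fisher exact adjusted p = 0.525).

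Mouse counterparts of human DUX4 target genes had a peak in 18 of 34 cases (52.9%; odds ratio 2.96, Fisher exact adjusted p = 0.00482), led by the *Zscan4* copies and *Pramel11*. This list shares 15 genes with the 2-cell list. Outside the shared genes 4 of 19 had a peak (21.1%; odds ratio 0.764, Fisher exact p = 0.618), and these were *Ilvbl*, *Wfdc3*, *Mbd3l2* and *Rfpl4b*. *Ccna1*, *Kdm4d*, *Slc34a2* and the *Trim43* genes had none within 5 kb. Against shifted peaks the count of 18 lay above the expected range (mean 8.62, 4 to 14, adjusted permutation p = 0.0220). With length matching the Fisher call was kept (odds ratio 3.44). The call was lost with 1 gene per 200 kb of chromosome (odds ratio 2.38, Fisher exact adjusted p = 0.0755; 1.08 and 0.932 with any gene per block), with protein-coding members alone (2.16, 0.128) and within 20 kb (1.61, 0.407), and in the gene body the direction was reversed (0.900, adjusted p = 1).

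Obox and other paired-like homeobox genes had a peak in 30 of 68 cases (44.1%; odds ratio 2.09, Fisher exact adjusted p = 0.00856). The *Obox* genes and pseudogenes, a homeobox cluster of the oocyte and early embryo, accounted for 28 of 53, and the remaining paired-like genes for 2 of 15. All 6 protein-coding *Obox* genes, a part picked out after its values were seen and lying in a single cluster, had a peak. As at *Zscan4*, the handling of reads shared between similar copies is not given in the sources used here, so the share of each *Obox* copy is uncertain. The strongest was *Obox4-ps28*, with 137-fold enrichment 2569 bp from the gene, and *Obox1* had 43.0-fold enrichment. Against shifted peaks, which keep the clustering, the count of 30 lay above the expected range (mean 13.8, 4 to 23, adjusted permutation p = 0.0220). With 1 gene per 200 kb the direction was reversed (odds ratio 0.709, Fisher exact adjusted p = 0.499; 0.591 and 0.478 with any gene per block), as it was in the gene body (0.218, adjusted p = 2.89e-05). For the whole list the call was also lost with protein-coding members alone (1.66, Fisher exact adjusted p = 0.360), within 1 kb (1.74, 0.306), within 20 kb (1.88, 0.0504) and in the strongest 10% of peaks (3.10, 0.0514). The gene body setting was not matched for length, and with length matching the call was kept (odds ratio 2.61).

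Housekeeping genes had a peak in 10 of 18 cases (55.6%, interval 30.8 to 78.5%; odds ratio 3.26, Fisher exact adjusted p = 0.0261). Examples were *Hprt*, of purine salvage, at 24.5-fold, *Polr2a*, the largest subunit of RNA polymerase II, at 17.0-fold, and *Ppia* at 10.2-fold. Their best peaks had a median fold enrichment of 7.58 against 8.98 for other coding genes (mean log2 difference −0.204, adjusted permutation p of that difference = 0.599). Against shifted peaks the count of 10 lay above the expected range (mean 4.54, 1 to 8, adjusted permutation p = 0.0220). With length matching the Fisher call was kept (odds ratio 4.09). The call was lost in the strongest 10% (odds ratio 2.55, Fisher exact adjusted p = 0.584), within 20 kb (3.05, 0.115), in the gene body (1.70, 0.493) and with 1 gene per 200 kb (2.94, 0.0755; 1.33 and 0.878 with any gene per block).

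Skeletal muscle genes, the programme of the host cells, had a peak in 14 of 35 cases (odds ratio 1.78, adjusted p = 0.200) and did not pass the Fisher exact test. Values there included 33.4-fold near *Myh4*, a fast myosin heavy chain, 24.9-fold near *Des*, the muscle intermediate filament, and 18.4-fold near the regulator *Myf6*. Genes of p53 signalling and cell death had a peak in 7 of 16 cases (odds ratio 2.08, Fisher exact adjusted p = 0.224), among them *Pmaip1* at 29.1-fold and *Casp8* at 22.5-fold. Hox genes had a peak in 14 of 39 (odds ratio 1.5, Fisher exact adjusted p = 0.309), ribosomal protein genes in 18 of 85 (0.721, 0.273) and pluripotency genes in 3 of 20 (0.526, 0.316). The 3 pluripotency genes were *Klf5* (29.1-fold), *Nr5a2* (7.78-fold) and *Esrrb* (4.59-fold).

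Olfactory receptor genes had a peak in 187 of 1117 cases (16.7%; odds ratio 0.516, Fisher exact adjusted p = 5.73e-17) and vomeronasal receptor genes in 48 of 357 (13.4%; odds ratio 0.408, adjusted p = 5.92e-10). The Fisher test alone did not carry these calls, because it also called the olfactory list in 100 and the vomeronasal list in 62 of 100 random placements of the peaks. With length matching the odds ratios rose, to 0.756 for olfactory and 0.486 for vomeronasal genes, so part of each lower share went with gene length. Against shifted peaks, which keep the genes' sizes and clustering, the olfactory count lay within the expected range (mean 213, 172 to 252, adjusted permutation p = 0.367), and in 200 kb blocks the Fisher exact result depended on the counting, with an odds ratio of 0.404 for 1 gene per block (adjusted p = 3.15e-06) and 1.15 for any gene per block (adjusted p = 0.510). The vomeronasal count lay below it (mean 75.1, 55 to 96, adjusted permutation p = 0.0220). The shifts took no account of where reads can be mapped, so this lower count does not show that the chimera avoids these genes.

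**Figure D3:**
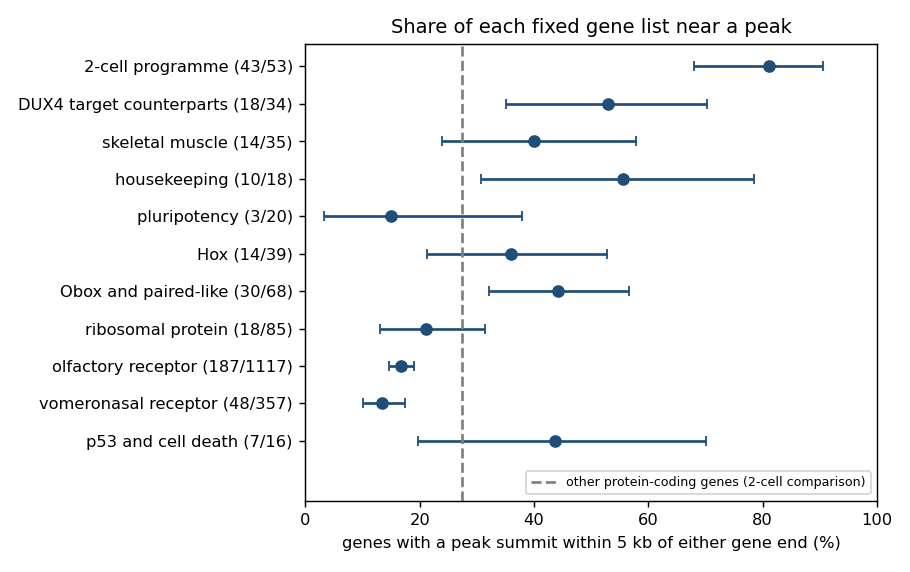
Percent of the genes of each fixed list with a peak summit within 5 kb of either gene end. Points are shares, bars are exact binomial 95% intervals that cover counting error only, numbers beside the names are genes with a peak and genes in the list, and the dashed line is the 27.4% of other protein-coding genes. The 2-cell list stands highest, at 81.1%.

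Peak density differed between chromosomes. Chromosome 15 had 28.6 peaks per Mb (counting SE 0.533) and chromosome 4 had 24.7 (SE 0.402), while the other 17 autosomes had 17.0 to 23.7 and the X chromosome had 13.9 (SE 0.289). The control-derived local background lay above its genome-wide floor in 81.3% of peaks on chromosome 15 and 43.1% on chromosome 4, against 14.2 to 18.9% on the other 17 autosomes.

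**Figure D4:**
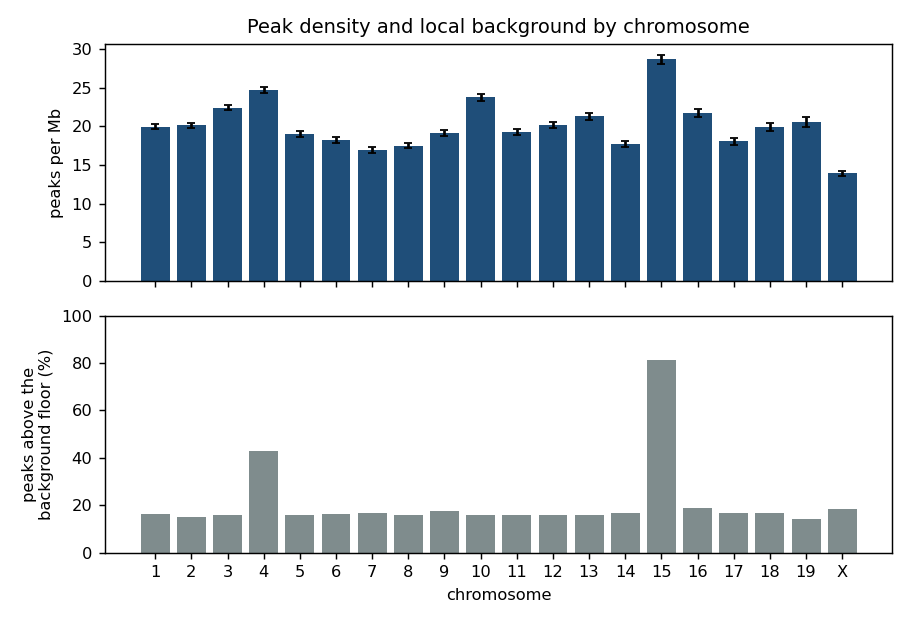
Peaks per Mb of each chromosome (upper panel, bars with counting SE) and percent of its peaks whose local background lies above the genome-wide floor (lower panel). Chromosome 15 is highest in both, at 28.6 peaks per Mb and 81.3%, followed by chromosome 4 at 24.7 and 43.1%.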

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

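The tests of chromosome 15's background, of the high-background peaks and of 2-cell genes without family-mates were chosen only after the result was seen. Chromosomes outside the main comparisons held single peaks: 1 on the mitochondrial chromosome (4.17-fold over a background of 722 fragments) and 1 on chromosome Y (4.26-fold over a background of 18.5). Both backgrounds lay far above the floor of 4.01 fragments. Reads shared with similar sequence elsewhere were not examined, so neither peak shows enrichment particular to its chromosome.

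Chromosome 15 had more peaks per Mb than every other chromosome tested. Its local background, which comes from the control, lay above the floor in 81.3% of its peaks, and in most peaks of each of its 21 tested bins of 5 Mb, so the control library carried more fragments there. After dividing its pileups by 1.5, the ratio to the other autosomes at a fixed rank of peaks per Mb, it had 14.8 peaks of pileup 30 or more per Mb, inside the 12.3 to 17.2 of the other 17 autosomes. The divisor came from the same peaks, so that value decides nothing, and how much of the density depth accounts for stays open. From the background alone, extra copies of the chromosome in this clone may raise its depth, and no biological explanation was tested.

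Of the 10 strongest peaks by −log10 p, 4 had a local background of 10 fragments or more, and all 4 left the 10 strongest by fold enrichment. A candidate explanation for those 4 is that sequence collapsed in the assembly or shared by many copies piles up reads in both libraries. Binding to such repeats was not tested, since no sequence was used here.

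Members of the 2-cell list had a nearby peak more often than other genes. Placement of the peaks beside clustered genes was argued against by the shifts, of which 0 of 1000 gave as many members. Reads shared between list members were argued against as the source of all the peaks by the 6 members without a family-mate there. Of those 6, 5 had a peak (odds ratio 9.71, Fisher exact p = 0.00717). Similar copies outside the list were not searched for, so reads shared with such copies are not excluded. The 5 peaks ranged from 8.78-fold at *Nelfa* to 34.9-fold at *Zfp352*, against a median of 8.98 for other coding genes with a peak. Of the 22 members alone in their 200 kb block, 18 had a peak (odds ratio 10.9, Fisher exact p = 1.71e-07), but 13 of those 18 were outside that set of single genes, so being alone in a block does not rule out reads shared with copies elsewhere. For the family members, copying among near-identical paralogues and binding at each copy cannot be told apart here, since the handling of reads that map to several places is not given in the sources used here.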

How the results depend on the processing

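The tests with length matching, protein-coding members alone, high-background peaks removed and chromosomes 4 and 15 removed were chosen only after the data were seen. A count by 200 kb blocks was planned, but its way of counting was changed after values were seen. Of 135 recomputed test results, 101 kept their direction and side of the threshold. The vomeronasal list did so under all 11 settings (odds ratio 0.158 to 0.486), but all 11 use the Fisher test, which called this list in 62 of 100 random placements, so they do not show that its call is robust. The 2-cell list did so under 10 of 11, with odds ratios up to 34.3 and the exception of the gene body (1.29). The cause of the changes below was not tested. Counting 1 gene per 200 kb gave 0.709 for Obox and paired-like, 2.38 for DUX4-target and 2.94 for housekeeping genes. That counting, the first gene of each block, replaced an earlier one after its values were seen. The earlier one, any gene per block, favours gene-dense blocks and gave 0.591 for Obox, 1.15 for olfactory (reversed), 0.851 for p53 and cell death (reversed), 0.243 for pluripotency (newly called, Fisher exact adjusted p = 0.0226), 0.309 for ribosomal protein (newly called, 6.69e-06), 1.08 for DUX4-target and 1.33 for housekeeping genes. The gene body gave 0.900 for DUX4-target, 0.986 for muscle, 0.407 for Hox, 0.218 for Obox, 0.143 for ribosomal protein (newly called) and 1.70 for housekeeping genes. That setting counts summits inside the gene span and was not matched for length, so a low value there does not show that a list lacks peaks. The strongest 10% gave 2.29 for pluripotency, 0.376 for Hox, 2.55 for housekeeping, 3.10 for Obox, 1.05 for summits inside a gene and 0.968 for summits within 1 kb of a coding gene end. Within 1 kb gave 1.68 for pluripotency, 1.01 for ribosomal protein and 1.74 for Obox genes, and within 20 kb gave 1.61 for DUX4-target, 3.05 for housekeeping and 1.88 for Obox genes. Protein-coding members alone gave 2.16 for DUX4-target and 1.66 for Obox genes, and length matching gave 1.04 for ribosomal protein genes. Under length matching the calls of the 2-cell (14.7), housekeeping (4.09), DUX4-target (3.44) and Obox (2.61) lists were kept. Flanks gave 0.983 for summits inside a gene, and a 5 kb window gave 0.991 for summits near a coding gene end. A fold enrichment of at least 10 left 19557 peaks. No paired analysis was possible because each group had 1 library, which also ruled out leaving replicates out. Motif, substitution, repeat and GC-matched alternatives were not run, since no sequence was used here. Depth was not varied, since reads were not used here.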

Other observations

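The tests in this part, on families by symbol and on peak spacing, were chosen only after peaks had been examined. Genes were grouped by the stem of their symbol, and 788 families were tested for members with a peak of the strongest 10% within 5 kb (2-sided Fisher exact test, Benjamini-Hochberg adjusted), and 6 passed. Zinc-finger genes of the *Zscan* stem had such a peak in 10 of 21 cases (Fisher exact adjusted p = 1.39e-07), 9 of them *Zscan4* copies and the other one *Zscan26*. Prame-like genes had one in 11 of 48 cases, at 11 distinct peaks of 26.7-fold to 152-fold (Fisher exact adjusted p = 6.61e-05). In both families, reads shared between similar copies could place peaks at several of them, and their handling is not given in the sources used here. The members of each family are therefore not independent. Histone genes followed, with 6 of 19 *H2ac* genes (Fisher exact adjusted p = 0.00367) and 5 of 16 *H2bc* genes (adjusted p = 0.0161), but neighbouring members shared peaks. Each group rested on 4 distinct peaks of 28.7-fold to 49.5-fold, 3 of which served both, so the 2 results are not separate. All 9 *Ugt1a* genes counted through 1 shared peak of 21.5-fold, which makes that family's test uninformative. The only family that passed in the other direction was the olfactory *Olfr* stem (15 of 1427, odds ratio 0.308, Fisher exact adjusted p = 9.22e-06), but the test of the olfactory list in the report also called it in 100 of 100 random placements, and the family test was not checked for that bias.

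Full-length endogenous retroviruses such as MERVL carry a long terminal repeat at each end, and binding at both was a hypothesis for pairs of strong peaks a fixed distance apart. In the strongest 10%, 29 neighbouring pairs lay 5.5 to 6.5 kb apart, against 34 and 24 in the 1 kb bins on either side (1-sided exact binomial p = 0.540). The spacing of all peaks had been seen before (1221 pairs, against 1290 and 1100). The test showed no excess, and with so few pairs a modest one could not be excluded. The handling of reads that map to several places is not given either, so the test cannot exclude binding at both repeats.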
